A study of Rattus norvegicus with 15 samples.

How the data were processed

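The authors isolated total RNA and sequenced it on an Illumina platform with standard Illumina library protocols, per the sample labels. HISAT2 (version not given in the sources used here) and StringTie 1.2.3 are named in the submitters' processing notes. The deposited expression table gives FPKM per gene and library, per the file headers. Its genes carry Ensembl rat identifiers, symbols and positions, and the genome build is not given in the sources used here. The table lists 12169 protein-coding genes, each with a group mean above 0.5 FPKM in at least 1 group, as found from the values. The authors also deposited lists of changed genes for 6 of the 10 possible pairs of groups, with log2 fold changes. These log2 values equal the difference of the group means of log2(FPKM + 1), as checked on the values. The deposited lists hold a ratio (fold change), a p-value and a q-value per gene, and the test behind them is not named in the file headers. All listed genes have a fold of at least 1.5 and a p-value of at most 0.0498. No counts were used, so the depth is unknown and no counting interval was computed.

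Groups were taken from the sample titles: BMSC, shLuci, shRac1, shLuci+OGD and shRac1+OGD, each with 3 replicates. Genes with at least 1 FPKM in at least 3 of the 15 libraries were kept, which left 11515 and removed 654. FPKM were used without further scaling as log2(FPKM + 0.5). Fold changes are on this scale, which understates changes of genes with low FPKM. Each contrast was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with all 15 libraries in a single fit of 5 group means and 10 residual degrees of freedom. P-values are two-sided and were adjusted by Benjamini and Hochberg over the genes of a contrast, and a gene was called at an adjusted p below 0.05. Error values after log2 changes are the standard errors of limma. Rac1 was also tested with an exact permutation of 3 against 3 libraries, for which the smallest p is 0.1. Genes listed at 0 in part of the libraries, with a mean above 10 FPKM over all 15, get no fold (6 genes). The 3 of them with a gene name rather than an accession or locus number are given per library.

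Gene groups were tested with camera from limma on 31 lists fixed before the data were examined, with an inter-gene correlation of 0.01, adjusted over the lists of a contrast. A list needed 5 tested members, which 26 lists had. Counts of called members are given over all genes tested and adjusted over the list alone. The genes named were chosen by a rule fixed at the same time, separately for each of the 6 main contrasts. The rule takes Rac1, Rac2 and Rac3, and the 10 called genes with the largest rise and the 10 with the largest fall. The latter need a symbol, at least 5 FPKM in the higher group and, except for the interaction, no overlap between the groups, which chance alone gives in 10% of comparisons of 3 with 3. From each list it takes up to 4 called members with the smallest p. Where camera called a list without a called member, it takes uncalled members with the smallest p. Exceptions are Cd68 and Fcer1g, named beside Cd14 after its change was seen, Ier3, chosen after its value was seen as the member of its list that was not called, and Nhp2, Polr2l and Zswim8, given per library as listed at 0 in part.

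The overlap of contrasts was compared with the number that independent lists of the same sizes share. That number does not allow for the spread per gene, which all contrasts share in the single fit. The hairpin and OGD pairs each compare contrasts with no library in common. The test was checked on simulated data drawn from the real means and spreads of the 11515 genes, with 50 genes changed at each of 4 sizes. With the spread pooled over the groups, 8 of 11295 unchanged genes were called for shLuci vs BMSC and 2 for shRac1 vs shLuci. With each group's own spread, 543 and 4 were called, and 5 for shRac1+OGD vs shLuci+OGD and 1 for the interaction. Of 50 genes with a simulated log2 change of 1, 34 were recovered for shLuci vs BMSC, 33 for shRac1 vs shLuci, 40 for shRac1+OGD vs shLuci+OGD and 27 for the interaction, again with each group's own spread. At a log2 change of 0.5, 25, 17, 14 and 5 of 50 were recovered in the same order. A simulated list of 20 genes moved by 0.5 was found by camera in each case, with p-values up to 1.31e-16. The simulated genes were drawn independently of each other and the 20 moved alike. This check therefore cannot show how camera fares with correlated genes.

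Alternatives were a pseudocount of 1 or 0.1, no filter, a filter on a mean of at least 5 FPKM, rescaling to a common total (TPM scale), median-of-ratios scaling and quantile normalization. Further alternatives were a fit to the compared groups only, a replicate block, library weights, no trend, an estimated inter-gene correlation, and leaving out each library in turn. Leaving BMSC replicate 2 out of the contrasts that do not include BMSC was added after its correlations had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome sequence was used, so hairpin sequences were not searched in the reads or in the transcripts. Some results for single genes and for a gene list are not reported here.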

Results

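Transcript levels were measured by RNA sequencing in mesenchymal stem cells from the femoral bone marrow of Sprague Dawley rats, at passages 3 to 5. The 15 libraries fall into 5 groups of 3: uninfected cells (BMSC), cells given a lentivirus with a hairpin against luciferase (shLuci, the control) or against Rac1 (shRac1), and both infected kinds after oxygen and glucose deprivation (OGD). OGD lasted 12 h at 1% O2 in medium without glucose and was followed by 24 h of reoxygenation. Values are FPKM for 12169 protein-coding genes, so the read depth behind them is unknown. The FPKM of a library summed to between 463945 and 516495 in 14 libraries and to 628685 in BMSC replicate 2, which also had 144 genes at 0 against 42 to 78 elsewhere and correlated less with its own group (mean r across genes of 0.915, against at least 0.949). The labels do not say that replicates came from separate cultures or animals, so each p-value measures only the spread between these samples.

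Rac1, the gene the hairpin targets, encodes a small GTPase that drives actin remodelling at the cell edge. Rac1 (ENSRNOG00000001068, chromosome 12, 13090172 to 13111873; the genome build is not given in the sources used here) stood at 151 ± 3.27 FPKM in BMSC, 156 ± 9.9 in shLuci and 147 ± 4.96 in the libraries labelled shRac1 (mean ± SD, n = 3 each). After OGD it stood at 156 ± 14.6 FPKM with shLuci and 155 ± 2.57 FPKM in the libraries labelled shRac1. Every library lay between 139.3 and 167.6 FPKM. The fold change of shRac1 against shLuci was 0.942 (95% confidence interval 0.839 to 1.06, limma adjusted p = 0.577; two-sided exact permutation p = 0.3, where 0.1 is the smallest possible). After OGD the fold was 0.998 (0.889 to 1.12, limma adjusted p = 1; exact permutation p = 0.9). With library weights, an alternative, the difference under normal culture was called (log2 change -0.07, limma adjusted p = 0.0295), but it stayed small. No marked loss of Rac1 transcript was therefore detected in the libraries labelled shRac1. Every direction given for a hairpin, for the control virus or for OGD within a hairpin rests on the sample titles alone. A closer look below leaves these titles in question for the groups without OGD. Rac3, its close relative, stayed between 0.713 and 1.92 FPKM as group means, and Rac2 is not among the genes listed.

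**Figure D1:**
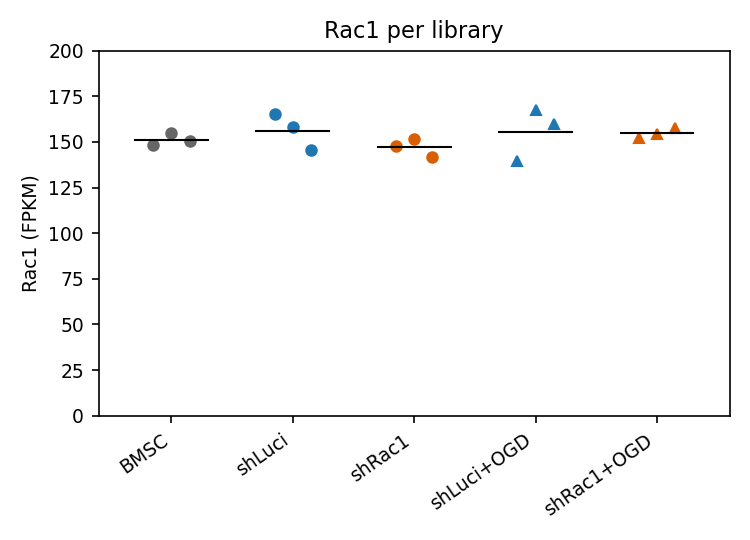
Rac1 in FPKM (vertical axis, starting at 0) for each of the 15 libraries by group (horizontal axis). Points are libraries, lines are means of 3, and all libraries lie between 139.3 and 167.6 FPKM.

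**Figure D2:**
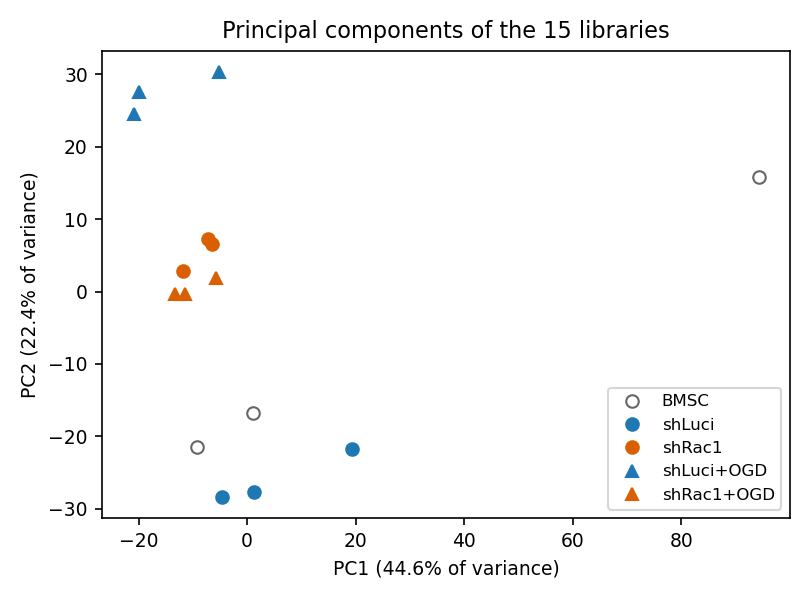
Principal components of the log2 values of the 15 libraries, with PC1 (44.6% of the variance) horizontal and PC2 (22.4%) vertical. Circles are libraries without OGD, triangles those with OGD, and BMSC replicate 2 lies alone at a PC1 score of 94.2.

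The libraries labelled shLuci were compared with BMSC to ask, if the sample titles hold, what the control virus alone changes. Mgp, which encodes matrix Gla protein, a secreted inhibitor of calcification, rose from 7.41 ± 2.6 to 172 ± 12.8 FPKM (mean ± SD, n = 3 each), a log2 change of 4.49 (SE 0.22, limma adjusted p = 2.24e-07). Cd24, a surface glycoprotein, rose from 1.79 ± 0.158 to 13.8 ± 0.517 FPKM, and Nov, a secreted matricellular protein, from 13.4 ± 3.15 to 64.4 ± 2.01 FPKM. Chac1, an ATF4 target that degrades glutathione, fell from 75.1 ± 11.3 to 25.9 ± 2.44 FPKM (log2 change -1.51, SE 0.11, limma adjusted p = 2.79e-06). Nkd1, an inhibitor of Wnt signalling, fell by 2.11 and Panx3, a channel of bone cells, fell by 2.13 on the log2 scale. Of 28 tested ATF4 targets of the integrated stress response, 16 fell, 0 rose and 12 were not called (21 fell and 1 rose when adjusted over the list alone), among them Atf3, Sesn2 and Ppp1r15a with log2 changes of -1.28, -1.19 and -1.07. Camera placed this list below the other genes at adjusted p = 2.03e-21, and at adjusted p = 0.0101 with an estimated correlation. Contractile genes of the SRF family, Actg2 (-1.53) and Cnn1 (-1.12) among them, fell in 7 of 22 cases with 0 rising (8 adjusted over the list alone; camera adjusted p = 2.4e-05, and adjusted p = 0.0135 with an estimated correlation). Mitotic genes rose in 15 of 26 cases with 0 falling (19 adjusted over the list alone), Plk1 (0.56) and Nusap1 (0.62) among them, at camera adjusted p = 8.47e-08 (4.55e-07 without BMSC replicate 2), but adjusted p = 0.111 with an estimated correlation. DNA replication genes rose in 8 of 28 cases (11 adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.0724 with an estimated correlation; 0.0592 without BMSC replicate 3). Genes of cholesterol synthesis rose in 6 of 21 (8 adjusted over the list alone; camera adjusted p = 0.00186, and adjusted p = 0.124 with an estimated correlation). Targets of NRF2 fell in 4 of 21 and rose in 1 (the same numbers adjusted over the list alone; camera adjusted p = 0.00186, but adjusted p = 0.148 with an estimated correlation, and 0.113 without BMSC replicate 2). Folding factors fell in 2 of 20 (2 adjusted over the list alone; camera adjusted p = 0.0222, but adjusted p = 0.111 with an estimated correlation), a call lost without BMSC replicate 1 (0.0611) or replicate 3 (0.0544). Mitochondrially encoded genes fell in 2 of 12 (2 adjusted over the list alone; camera adjusted p = 0.025, but adjusted p = 0.305 with an estimated correlation), a call lost without BMSC replicate 3 (0.121) or shLuci replicate 2 (0.105). Quantile normalization ended the calls of the last 2 lists (0.539 and 0.637). Ribosomal protein genes had no called member among 45, and camera placed them lower at adjusted p = 0.000731, but adjusted p = 0.803 with an estimated correlation, and higher at 0.00497 without BMSC replicate 2, so no direction is drawn for them. Nhp2 was listed at 0 in all 3 BMSC libraries and at 56.2 to 65.1 FPKM in the 3 shLuci libraries, and it was also listed at 0 in shRac1+OGD replicate 1.

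In that comparison limma called 1644 of 11515 genes, 1150 higher and 494 lower. The median of all genes lay at 0.11 on the log2 scale, and median-of-ratios scaling, which removes that shift, gave 758 higher and 713 lower. BMSC replicate 2 decided much of the count: 3686 genes were called without it, 1605 of them among the 1644, whereas a fit to these 2 groups alone called 181. Leaving out shLuci replicate 2 gave 1031. In simulated data with each group's own spread, 543 of 11295 unchanged genes were called in this comparison, against 1 to 5 in the 3 other contrasts simulated, none of which holds BMSC. These 543 were 80.6% of the 674 genes called there, a share that depends on how few genes were changed in the simulation. Adjusted p-values for shLuci vs BMSC are therefore too small for part of the genes. The other contrasts with BMSC were not simulated.

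The libraries labelled shRac1 were compared with those labelled shLuci to ask what the Rac1 hairpin changes under normal culture. Mgp (ENSRNOG00000005695, chromosome 4, 170856751 to 170860225) fell from 172 ± 12.8 to 0.409 ± 0.255 FPKM (n = 3 each, log2 change -7.61, SE 0.22, limma adjusted p = 6.42e-10). Rgs16, which shortens G protein signals, fell from 124 ± 8.39 to 14.7 ± 0.0839 FPKM, and Ccl2, a chemokine that draws monocytes, from 22.7 ± 0.556 to 3.01 ± 0.788 FPKM. Msln (ENSRNOG00000019445, chromosome 10, 15119663 to 15125408), which encodes the surface protein mesothelin, rose from 0.887 ± 0.18 to 11.1 ± 0.65 FPKM (log2 change 3.07, SE 0.12, limma adjusted p = 7.47e-09). Aldh3a1, an aldehyde dehydrogenase, rose from 0.972 ± 0.139 to 8.11 ± 0.25 FPKM. Igfbp6, Hspb8 and the Wnt antagonist Sfrp1 rose by 2.96, 2.47 and 2.36 on the log2 scale. Nox4 and Cyba, subunits of an NADPH oxidase, both fell (limma adjusted p = 6.55e-07 and 0.00123), with too few tested members in that list for camera. Nox4 stood at 1.43 FPKM in BMSC, 5.72 in shLuci and 1.43 in shRac1, so shRac1 was level with BMSC. Mgp and Msln, by contrast, lay beyond their BMSC means of 7.41 and 2.09 FPKM. Of the ATF4 targets, 9 rose, 0 fell and 19 were not called (10 rose and 1 fell when adjusted over the list alone), Chac1 (1.59) and Atf3 (1.16) among them, at camera adjusted p = 0.000932, but adjusted p = 0.231 with an estimated correlation. Chac1 stood at 75.1 FPKM in BMSC, 25.9 in shLuci and 78.6 in shRac1, and Atf3 at 12.2, 4.74 and 11.2. Against BMSC, 8 of 28 ATF4 targets were called lower in shRac1 and 0 higher. Folding factors of the endoplasmic reticulum rose in 4 of 20 cases with 0 falling (4 adjusted over the list alone), Herpud1 (0.59) and Pdia6 (0.51) among them, at camera adjusted p = 0.00326, but adjusted p = 0.131 with an estimated correlation. Cholesterol synthesis genes rose in 5 of 21 cases (6 adjusted over the list alone) and mitotic genes fell in 6 of 26 (7 adjusted over the list alone), each at camera adjusted p = 0.00105. With an estimated correlation the cholesterol list had adjusted p = 0.231 and the mitotic list adjusted p = 0.367. Mitotic genes were not lower in shRac1 than in BMSC: 2 of 26 were called higher and 0 lower. Of the folding factors, 2 of 20 were called higher in shRac1 than in BMSC and 0 lower. Between shRac1 and shLuci limma called 1928 genes, 797 higher and 1131 lower, of which 455 changed at least 2-fold. Without BMSC replicate 2, which adds to the pooled spread, the count was 4296 (1952 higher, 2344 lower).

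OGD was first examined in the cells labelled shLuci, to ask what remains of the response to deprivation after reoxygenation. Immediate early genes, which growth factors and handling switch on within minutes, all fell: Fos (ENSRNOG00000008015, chromosome 6, 109300433 to 109303299) went from 157 ± 0.976 to 13.4 ± 1.13 FPKM (n = 3 each, log2 change -3.50, SE 0.08, limma adjusted p = 3.57e-11). Egr1 fell by 2.17 and Egr2 fell by 2.45 on the log2 scale. Acta2, the smooth muscle actin, fell from 3470 ± 313 to 1500 ± 146 FPKM (log2 change -1.21, SE 0.13, limma adjusted p = 1.99e-05). Alpl, an early bone enzyme, fell by 2.59 while the matrix protein gene Spp1 rose by 1.26. Xdh, which makes uric acid and superoxide, rose from 1.02 ± 0.04 to 18.5 ± 0.54 FPKM, and Olfm1 from 0.54 ± 0.18 to 13.3 ± 1.07 FPKM. All 15 tested immediate early genes fell (15 adjusted over the list alone; camera adjusted p = 7.01e-21, and adjusted p = 0.00108 with an estimated correlation). Contractile genes fell in 8 of 22 cases with 0 rising (8 adjusted over the list alone; camera adjusted p = 5.41e-06, and adjusted p = 0.00943 with an estimated correlation). YAP targets fell in 8 of 13 with 0 rising (8 adjusted over the list alone), Tgfb2 (-2.08), Amotl2 (-1.10) and Cyr61 (-1.05) among them, at camera adjusted p = 1.66e-07, but adjusted p = 0.0668 with an estimated correlation. ATF4 targets fell in 12 of 28 and rose in 1 (the same numbers adjusted over the list alone; camera adjusted p = 5.41e-06, but adjusted p = 0.0668 with an estimated correlation). Glycolytic enzymes rose in 8 of 17 with 0 falling (8 adjusted over the list alone), Pfkm (0.93) and Pkm (0.43) among them, at camera adjusted p = 0.00604, but adjusted p = 0.259 with an estimated correlation. Genes induced by hypoxia-inducible factor went both ways, with 8 rising (Ndrg1, 1.05), 5 falling (Car9, -1.08; Slc16a3, -3.41) and 12 not called (9 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.88). Interferon-stimulated genes rose in 8 of 19 and fell in 2 (11 and 2 adjusted over the list alone), Irf1 and Irf7 (0.85 each) among them, at camera adjusted p = 0.0114, but adjusted p = 0.0547 with an estimated correlation. Among markers of other cells, 1 of 3 tested for macrophages and the only 1 tested for erythroid cells and neutrophils rose. Of 3 endothelial markers 1 fell and 0 rose. Trophic factors fell in 10 of 23 and rose in 4 (the same numbers adjusted over the list alone), Gas6 (-1.98) and Cxcl12 (-1.61) among the falls, at camera adjusted p = 0.00712, but adjusted p = 0.0668 with an estimated correlation. Targets of NF-kB fell in 6 of 14 with 0 rising (6 adjusted over the list alone), Cxcl1 (-1.85) and Lif (-3.08) among them, at camera adjusted p = 0.00371, but adjusted p = 0.0547 with an estimated correlation. DNA replication genes fell in 4 of 28 (4 adjusted over the list alone; camera adjusted p = 0.00419, but adjusted p = 0.0547 with an estimated correlation) and p53 targets fell in 7 of 22 and rose in 3 (7 and 4 adjusted over the list alone; camera adjusted p = 0.00712, but adjusted p = 0.0547 with an estimated correlation).

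In the same comparison cholesterol synthesis genes rose in 6 of 21 (9 adjusted over the list alone), Srebf2 (0.57) among them, at camera adjusted p = 0.00399, but adjusted p = 0.0916 with an estimated correlation. Matrix genes fell in 7 of 22 and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00712, but adjusted p = 0.642 with an estimated correlation). Folding factors fell in 3 of 20 (3 adjusted over the list alone; camera adjusted p = 0.0217, but adjusted p = 0.0668 with an estimated correlation). Mitotic genes fell in 3 of 26 (1 adjusted over the list alone; camera adjusted p = 0.034, but adjusted p = 0.546 with an estimated correlation), a call lost without shLuci replicate 3 (0.0849), shLuci+OGD replicate 2 (0.1) or shLuci+OGD replicate 3 (0.0568). Limma called 2564 genes, 1507 higher and 1057 lower, against 1125 higher and 1344 lower with median-of-ratios scaling and 3273 higher and 1986 lower without BMSC replicate 2.

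OGD was examined likewise in the cells labelled shRac1. Fos fell from 169 ± 7.15 to 5.36 ± 0.528 FPKM (n = 3 each, log2 change -4.86, SE 0.08, limma adjusted p = 1.29e-12), and Egr1, Klf4 and Dusp1 fell by 2.47, 2.35 and 1.21 on the log2 scale. Mgp rose from 0.409 ± 0.255 to 9.63 ± 0.488 FPKM (log2 change 3.52, SE 0.22, limma adjusted p = 7.33e-07), and Ccl2 from 3.01 ± 0.788 to 24.8 ± 1.2 FPKM. Atf3, a stress transcription factor, fell from 11.2 ± 0.339 to 2.33 ± 0.0781 FPKM. Col14a1, a collagen that coats fibrils, fell by 2.42 on the log2 scale. Of 15 immediate early genes 14 fell (14 adjusted over the list alone; camera adjusted p = 4.81e-30, and adjusted p = 0.000219 with an estimated correlation), while Ier3 was not called. ATF4 targets fell in 12 of 28 cases and rose in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.57e-15, and adjusted p = 0.0116 with an estimated correlation). Folding factors fell in 6 of 20 with 0 rising (7 adjusted over the list alone), Herpud1 (-0.87) and Hspa5 (-0.55) among them, at camera adjusted p = 2.79e-07, and adjusted p = 0.00264 with an estimated correlation. DNA replication genes fell in 4 of 28 with 0 rising (4 adjusted over the list alone; camera adjusted p = 0.00275, and adjusted p = 0.0298 with an estimated correlation). Targets of hypoxia-inducible factor rose in 4 of 25 with 0 falling (6 adjusted over the list alone), Ddit4 (1.05) among them, at camera adjusted p = 0.0242, but adjusted p = 0.372 with an estimated correlation. Glycolytic enzymes rose in 3 of 17 (6 adjusted over the list alone; camera adjusted p = 0.0161, but adjusted p = 0.444 with an estimated correlation, and 0.0702 with median-of-ratios scaling). Interferon-stimulated genes fell in 4 of 19 and rose in 1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0173, but adjusted p = 0.0558 with an estimated correlation). Contractile genes fell in 2 of 22 (2 adjusted over the list alone; camera adjusted p = 0.0242, but adjusted p = 0.113 with an estimated correlation, and 0.0571 without shRac1 replicate 1). Limma called 1376 genes, 894 higher and 482 lower, against 717 higher and 604 lower with median-of-ratios scaling and 2209 higher and 1256 lower without BMSC replicate 2.

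**Figure D3:**
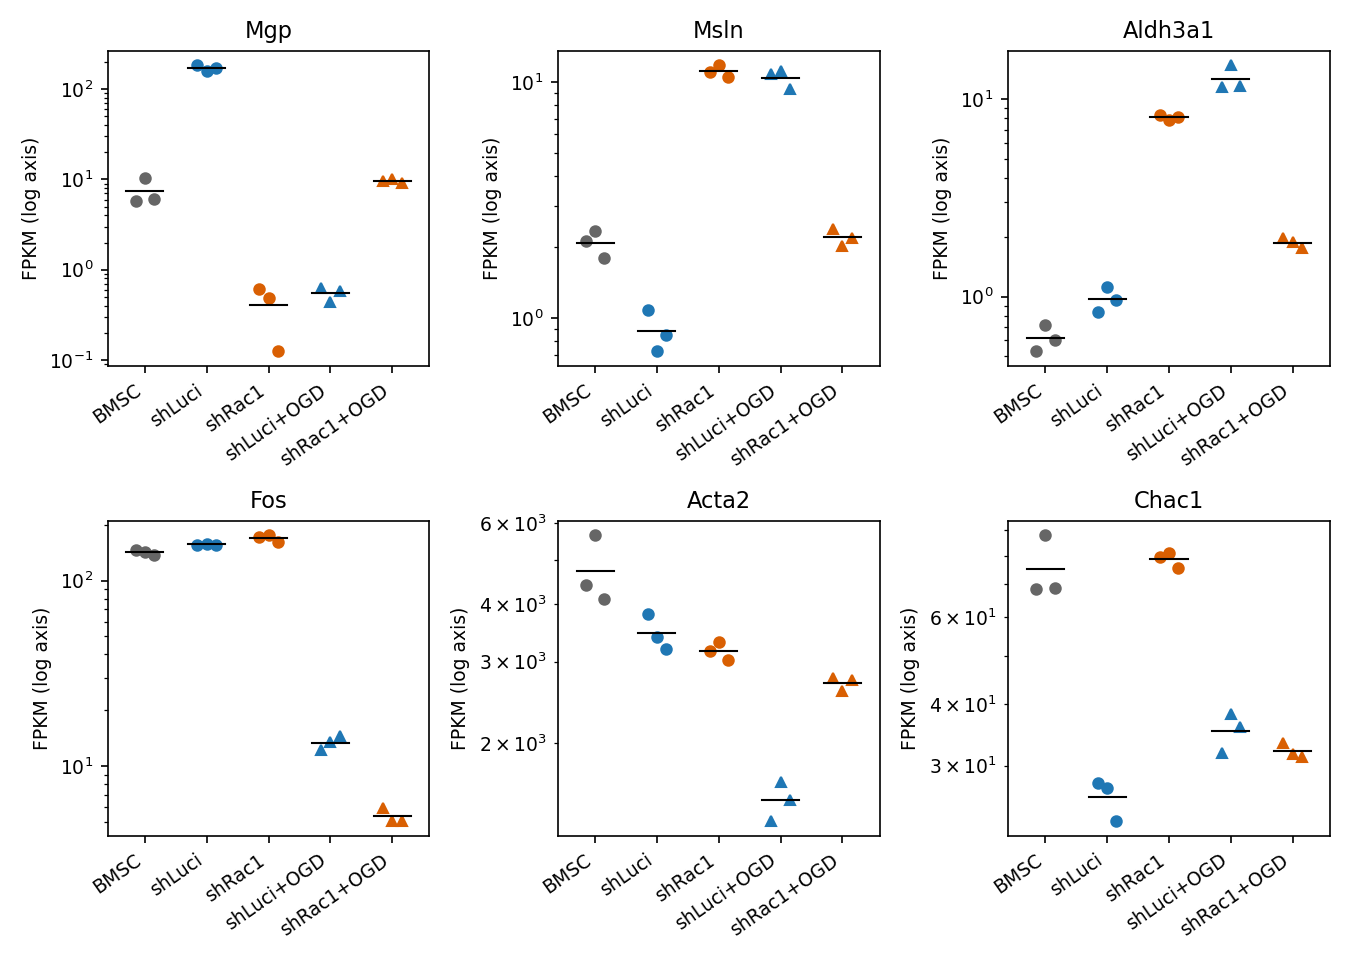
FPKM on a log axis (vertical) of Mgp, Msln, Aldh3a1, Fos, Acta2 and Chac1 in each of the 15 libraries by group (horizontal). Points are libraries and lines are means of 3, and Fos lies at 13.4 and 5.36 FPKM on average in the OGD groups, against 142 to 169 FPKM in the others.

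After OGD, the libraries labelled shRac1 were compared with those labelled shLuci, the contrast that asks what the Rac1 hairpin does to deprived cells. Mgp rose from 0.549 ± 0.103 to 9.63 ± 0.488 FPKM (n = 3 each, log2 change 3.28, SE 0.22, limma adjusted p = 2.16e-06) and the vasoconstrictor gene Edn1 from 3.73 ± 0.284 to 25.7 ± 0.69 FPKM. Acta2 (ENSRNOG00000058039, chromosome 1, 252537615 to 252550394) rose from 1500 ± 146 to 2700 ± 93.4 FPKM (log2 change 0.85, SE 0.13, limma adjusted p = 0.00117). Aldh3a1 (ENSRNOG00000002331, chromosome 10, 47490153 to 47499876) fell from 12.7 ± 1.87 to 1.87 ± 0.106 FPKM, and Msln and Xdh fell by 2.02 and 1.90 on the log2 scale. Contractile genes rose in 10 of 22 cases with 0 falling (13 adjusted over the list alone), Tpm1 (0.62) and Actg2 (1.18) among them, at camera adjusted p = 1.73e-12, and adjusted p = 0.000674 with an estimated correlation. YAP targets rose in 8 of 13 with 0 falling (9 adjusted over the list alone), Tgfb2 (1.34) and Ctgf (0.76) among them, at camera adjusted p = 1.81e-10, but adjusted p = 0.0815 with an estimated correlation. Interferon-stimulated genes fell in 6 of 19 with 0 rising (9 adjusted over the list alone), Irf7 (-0.91) and Psmb9 (-1.13) among them, at camera adjusted p = 2.14e-05, and adjusted p = 0.00586 with an estimated correlation. Cd14, a marker of macrophages, also fell, from 12.4 ± 0.551 to 8.91 ± 0.264 FPKM (log2 change -0.45, SE 0.11, limma adjusted p = 0.0209), while Cd68 and Fcer1g, the other tested markers of these cells, were not called. Targets of hypoxia-inducible factor rose in 4 of 25 and fell in 2 (7 and 2 adjusted over the list alone), Car9 (0.88) and Slc2a1 (0.52) among the rises, at camera adjusted p = 0.000574, but adjusted p = 0.105 with an estimated correlation. ATF4 targets rose in 3 of 28 (3 adjusted over the list alone; camera adjusted p = 0.00542, but adjusted p = 0.326 with an estimated correlation) and NF-kB targets in 3 of 14 (3 adjusted over the list alone; camera adjusted p = 0.00834, but adjusted p = 0.105 with an estimated correlation).

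In the same comparison trophic factors rose in 5 of 23 and fell in 2 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0347, but adjusted p = 0.159 with an estimated correlation). Targets of p53 rose in 4 of 22 with 0 falling (6 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0347, but adjusted p = 0.105 with an estimated correlation, and 0.0619 without shLuci+OGD replicate 1). Matrix genes rose in 3 of 22 and fell in 2 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0403, but adjusted p = 0.696 with an estimated correlation), a call lost without shLuci+OGD replicate 1 (0.217) or shRac1+OGD replicate 1 (0.0572). Mitotic genes fell in 1 of 26 (0 adjusted over the list alone; camera adjusted p = 0.0351, but adjusted p = 0.646 with an estimated correlation, and 0.109 without shLuci+OGD replicate 1). None of 45 ribosomal protein genes was called, although camera placed them lower at adjusted p = 0.0137, but adjusted p = 0.7 with an estimated correlation, and 0.0735 without shLuci+OGD replicate 2. Limma called 856 genes, 443 higher and 413 lower, against 508 higher and 323 lower with median-of-ratios scaling. The split turned round, with more genes, without BMSC replicate 2 (1048 higher, 1425 lower), with only the compared groups (900 and 1200) and with library weights (1396 and 2008), so no excess in either direction is drawn. Leaving out shRac1+OGD replicate 1 or replicate 2 lowered the count to 554 or 560.

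The hairpin contrasts before and after OGD share no library, and they moved many genes in opposite directions. Of the genes called in both, 482 went opposite ways and 48 the same way. Independent lists of these sizes would share 28.6 genes up then down, 43.5 down then up, 30.7 up in both and 40.6 down in both, and the data gave 216, 266, 31 and 17. Since the contrasts share each gene's estimate of spread, genes with a low spread are easier to call in both, whatever the direction. The log2 changes correlated at r = -0.51 (Pearson) and -0.34 (Spearman) across genes, which are not independent replicates. Mgp, Rgs16 and Rassf4 fell with the label shRac1 under normal culture and rose with it after OGD, whereas Msln, Aldh3a1 and Cdhr1 rose and then fell. The OGD contrasts shared 342 genes in direction (201 higher and 141 lower, against 117 and 44.2 for independent lists), and 370 went opposite ways (147 up then down and 223 down then up, against 63.1 and 82.1), with r = -0.08 (Pearson) and 0.01 (Spearman) across genes.

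**Figure D4:**
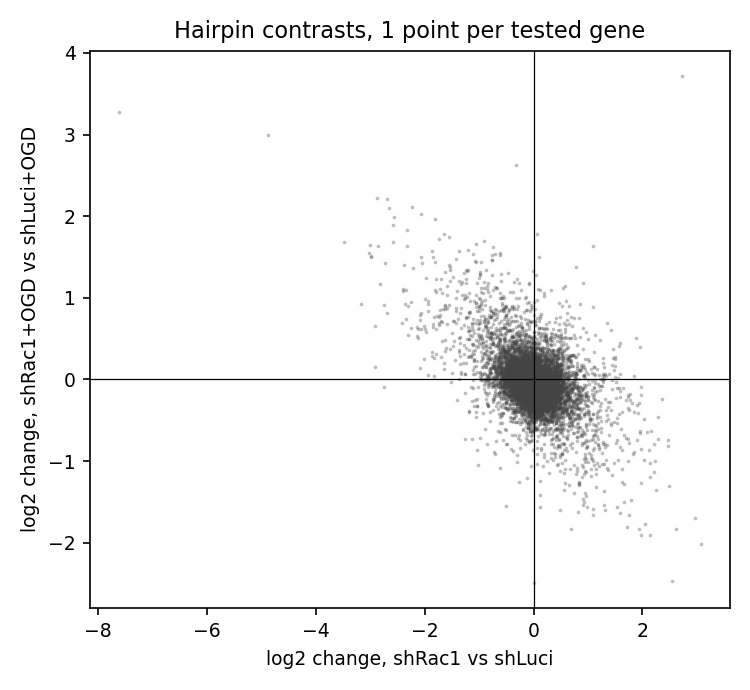
Log2 change of each of 11515 tested genes between libraries labelled shRac1 and shLuci, under normal culture (horizontal) and after OGD (vertical). Each point is a gene, and the changes run opposite to each other with r = -0.51.

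The difference between the hairpin contrasts was tested directly as an interaction. Limma called 1922 genes, 1022 with a more positive change after OGD and 900 with a more negative one. This split also turned round without BMSC replicate 2 (1995 and 2222), with only the compared groups (1984 and 2191) and with library weights (3069 and 3604). Rgs16, at 124 ± 8.39 and 14.7 ± 0.0839 FPKM with shLuci and shRac1 before OGD, stood at 12.2 ± 0.306 and 36.7 ± 1.85 FPKM after it (n = 3 each, limma adjusted p = 7.84e-11). Anpep, an aminopeptidase, stood at 2.19 ± 0.23 and 11.3 ± 1.14 FPKM before OGD and at 22.1 ± 0.522 and 5.57 ± 0.333 FPKM after it (limma adjusted p = 1.32e-09). Of 13 YAP targets 6 had a more positive change and 0 a more negative one (6 adjusted over the list alone), and of 19 interferon-stimulated genes 2 had a more positive and 9 a more negative change (the same numbers adjusted over the list alone). Among NF-kB targets 7 of 14 had a more positive and 2 a more negative change (the same numbers adjusted over the list alone).

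Further contrasts set groups against each other that differ in more than a single treatment. Limma called 1232 genes between the libraries labelled shRac1 and BMSC (736 higher, 496 lower), 1551 between shRac1+OGD and BMSC (1145 higher, 406 lower) and 1806 between shLuci+OGD and shRac1 (1229 higher, 577 lower). With median-of-ratios scaling these splits were 472 and 650, 553 and 635, and 690 and 821. The median of all genes lay at 0.15 on the log2 scale for shRac1+OGD against BMSC. The contrasts with BMSC depended on the wide spread of that group: fits to the 2 groups alone called 161 genes (88 higher, 73 lower) for shRac1 and 74 (34 and 40) for shRac1+OGD, whereas 2430 and 3028 were called without BMSC replicate 2. Leaving out shRac1 replicate 1, 2 or 3 gave 807, 749 or 727 for shRac1 against BMSC. For shRac1+OGD against BMSC the count was 2689 without BMSC replicate 1 and 850, 818 or 934 without shRac1+OGD replicate 1, 2 or 3. Without BMSC replicate 2, shLuci+OGD against shRac1 gave 4302.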

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

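The tests of the sample titles against the column letters, of a shift of the shLuci libraries, of the Rac1 level and of the FPKM scale of BMSC replicate 2 were chosen after those results had been seen. The others were planned.

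The change that goes with the label shRac1 differed between normal culture and OGD in 1922 genes by limma's interaction test. Among the largest interaction values on the log2 scale were those of Mgp (10.88), Rpl39l (7.87), S100a16 (5.17), Galnt3 (5.10), Aard (4.90), Kif26b (4.76), Rassf4 (4.65), Rgs16 (4.57), Serpinb6b (4.55) and Fstl3 (4.50). The most negative were Msln (-5.09), Aldh3a1 (-5.02), Igfbp6 (-4.65), Cdhr1 (-4.45), Anpep (-4.04), Xdh (-3.87), Mcpt8l2 (-3.78), Aspn (-3.76), Aspnl1 (-3.53) and Ptgs1 (-3.41). Some of the fixed lists also differed by camera. YAP targets were more positive after OGD at adjusted p = 0.000633 (0.318 with an estimated correlation), with Tgfb2 (2.21), Nuak2 (2.42), Ajuba (0.73) and Cyr61 (0.85) among them. Matrix genes were so at adjusted p = 0.0368 (0.794 with an estimated correlation), with Tnc (2.50), Postn (1.42) and Col11a1 (1.97) positive and Thbs2 (-2.09) negative. The matrix call ended when shLuci replicate 2 (0.0547), shRac1 replicate 2 (0.0564), shRac1 replicate 3 (0.0745) or shLuci+OGD replicate 1 (0.0828) was left out. NF-kB targets were more positive at adjusted p = 0.0128 (0.22 with an estimated correlation), with Ccl2 (3.66), Cxcl1 (1.55) and Lif (4.35) positive and Icam1 (-0.59) negative. Interferon-stimulated genes were more negative at adjusted p = 0.00236 (0.0587 with an estimated correlation), with Psmb9 (-2.10), Irf7 (-1.43), Psmb8 (-1.86) and Stat2 (-1.30). Cholesterol synthesis genes were more negative at adjusted p = 0.0128 (0.275 with an estimated correlation), with Srebf2 (-0.59) and Idi1 (-0.42).

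A single library did not produce the opposite hairpin contrasts, since their correlation stayed at -0.47 or below with each of the 12 libraries left out. A shift of the shLuci libraries alone is also argued against. The contrast shRac1 vs BMSC, which uses none of them, ran opposite to the hairpin contrast after OGD at r = -0.48 across genes. Both opposite contrasts use the shRac1 libraries, however. Without these, shLuci vs BMSC was close to unrelated to the hairpin contrast after OGD, at r = 0.08 (-0.05 without BMSC replicate 2). Whether the shRac1 libraries alone were shifted was not tested and stays open. Read the other way, BMSC vs shRac1 followed the hairpin contrast after OGD at r = 0.48, with 519 shared calls in the same direction against 45.5 for independent lists. That shLuci+OGD vs shRac1 followed shRac1+OGD vs BMSC at r = 0.49 rests on the same equality of differences and is not separate evidence. The same holds for the count of 38 interaction genes given next. A candidate explanation is that the letters heading the columns stand for other groups than the sample titles give. The 3 groups without OGD can be matched in 6 ways. Taking the shRac1 columns as control hairpin and the BMSC columns as Rac1 hairpin left 38 interaction genes, against 705 to 1922 for the others. The hairpin r of this matching was 0.48 (0.72 without BMSC replicate 2). Without that library the count under the titles as given rose from 1922 to 4217, and the counts under the other matchings were not made. Exchanging shLuci and shRac1 alone gave a hairpin r of 0.51 and left 705. A biological explanation, a hairpin effect that reverses under OGD, stays open and was not tested apart from this, and Rac1 does not decide, since its ratio was between 0.941 and 1.06 under each matching.

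Rac1 was close to level, although the shRac1 virus is meant to lower it, and only library weights called it lower in shRac1 vs shLuci (-0.07, limma adjusted p = 0.0295). Exchanged labels among the 5 groups would leave a group with low Rac1 only if the hairpin lowered the transcript in some group. The lowest group mean was 0.941 of the highest, so Rac1 does not speak for or against an exchange. The spread between libraries does not hide a halving, since the lower 95% bound of the fold was 0.839. Reads of related genes assigned to Rac1, loss of the hairpin from the cells, or an effect on protein without loss of transcript stay open, and none was tested.

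BMSC replicate 2 stood apart from the other 14 libraries. A different overall FPKM scale is argued against, as a single factor would move short and long genes alike, whereas its median log2 deviation was 1.15 higher in the shortest of 4 equal classes of loci than in the longest, against -0.18 to 0.27 for the other libraries. Its deviation from the other BMSC libraries correlated with the span of the gene's locus (Spearman -0.46 across genes), with a median log2 deviation of 0.47 in the shortest class and -0.69 in the longest, so coverage skewed towards short genes may account for much of it. Cells of another type stay open: 7 macrophage, endothelial and neutrophil markers had a median deviation of 0.44, at 0.277 to 22.2 FPKM, too low and too few to decide.

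Regrouping the libraries gave a limited check on each count. For the interaction, 1 of 100 splits, the real one, reached 1922 genes, and the highest other gave 705, the number that exchanging shLuci and shRac1 also gives. Apart from exchanges of whole groups, the splits mix libraries of groups that differ, which widens the residual spread and lowers the count. They therefore ask whether the groups differ at all, not whether the hairpin contrasts differ, and do not exclude chance for the interaction. The same mixing holds for the contrasts that follow. The 3 against 3 contrasts allow only 10 splits each, too few for a share under 0.05. For these the real count and the highest other were 1644 and 0 for shLuci vs BMSC, 1928 and 0 for shRac1 vs shLuci, 2564 and 0 for shLuci+OGD vs shLuci, and 856 and 0 for shRac1+OGD vs shLuci+OGD. They were 1376 and 0 for shRac1+OGD vs shRac1, 1232 and 1 for shRac1 vs BMSC, 1551 and 1 for shRac1+OGD vs BMSC, and 1806 and 0 for shLuci+OGD vs shRac1.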

How the results depend on the processing

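Leaving BMSC replicate 2 out of the contrasts without BMSC was chosen after its correlations had been seen, and the other alternatives were planned. Counts are given in the order shLuci vs BMSC, shRac1 vs shLuci, shLuci+OGD vs shLuci, shRac1+OGD vs shLuci+OGD, shRac1+OGD vs shRac1, interaction, shRac1 vs BMSC, shRac1+OGD vs BMSC and shLuci+OGD vs shRac1. A mean of at least 5 FPKM, which tests fewer genes, gave 1052, 1117, 1621, 470, 749, 1120, 739, 947 and 1103 genes. Library weights gave 6537, 8239, 6999, 3404, 6487, 6673, 5092, 5364 and 5577, and they also brought Rac1 in shRac1 vs shLuci (-0.07 on the log2 scale) past the threshold, at limma adjusted p = 0.0295; the cause was not tested. A fit to the compared groups only gave 181, 3731, 4050, 2100, 4367, 4175, 161, 74 and 3773: it is lower where BMSC is in the fit and higher where the wide spread of BMSC is left out.

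With single libraries left out, the counts ranged from 1031 to 3686, 1361 to 4296, 1944 to 5259, 554 to 2473, 928 to 3465, 1515 to 4217, 727 to 2430, 818 to 3028 and 1205 to 4302. The highest count of each came without BMSC replicate 2, whose removal lowers the pooled spread. Counts also moved by over 1.5 times without shLuci replicate 2 (1031 for shLuci vs BMSC), and without shRac1+OGD replicate 1 or 2 (554 and 560 for shRac1+OGD vs shLuci+OGD). They did so without shRac1 replicates 1, 2 and 3 (807, 749 and 727 for shRac1 vs BMSC), and for shRac1+OGD vs BMSC without BMSC replicate 1 (2689) or shRac1+OGD replicates 1, 2 and 3 (850, 818 and 934). Rac1 stayed between -0.14 and -0.05 in shRac1 vs shLuci and between -0.08 and 0.05 after OGD in these fits, with no call.

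The replicate numbers gave no general pairing of the libraries, although Polr2l was at 0 in replicate 1 of each infected group: correlations of deviations between libraries of the same number ran from -0.64 to 0.56, and 3 of 15 libraries correlated best with their own number. The replicate block gave 1479, 1790, 2403, 756, 1256, 1753, 1061, 1367 and 1624 genes, and no list lost its call.

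The 48 genes shared in direction by the hairpin contrasts became 30 on the TPM scale and 181 with only the compared groups, and the 482 opposite ones 230 with a mean of at least 5 FPKM and 1014 with only those groups. For the OGD contrasts the 342 shared genes became 201 and 1004 under these settings, and the 370 opposite ones 180 and 917. The cause was not tested for the TPM scale.

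The named genes, counted per contrast and without Rac1 and Rac3, were 627, a few of them ribosomal protein genes that were not called. Of these, 95 lost their call on the TPM scale, 68 with only the compared groups, 67 with quantile normalization, 36 with median-of-ratios scaling and 25 with the replicate block. The losses were 7 each without a trend and with a pseudocount of 0.1, 1 with a pseudocount of 1 and 0 without BMSC replicate 2, with library weights or with no filter. With a mean of at least 5 FPKM 4 of 497 named genes lost their call, and without another single library up to 45 of 452 (shLuci replicate 2) and 42 of 289 (shRac1+OGD replicate 1). None reversed in these.

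Of 51 list calls, 41 were lost with an estimated correlation. Quantile normalization ended 12: matrix genes in the interaction (adjusted p = 0.0837), shLuci+OGD vs shLuci (0.092) and shRac1+OGD vs shLuci+OGD (0.103), mitotic genes in the latter contrasts (0.053 and 0.0577), trophic factors and p53 targets in shRac1+OGD vs shLuci+OGD (0.0982 each), contractile genes in shRac1+OGD vs shRac1 (0.125), folding factors in shRac1 vs shLuci (0.0612), and folding factors (0.539), ribosomal (0.629) and mitochondrial genes (0.637) in shLuci vs BMSC. The TPM scale ended 4: cholesterol (0.066) and matrix genes (0.0612) in the interaction, mitotic genes in shRac1+OGD vs shLuci+OGD (0.0938) and folding factors in shLuci vs BMSC (0.121). Median-of-ratios scaling ended 3: matrix genes (0.0533) and trophic factors (0.0534) in shRac1+OGD vs shLuci+OGD and glycolysis in shRac1+OGD vs shRac1 (0.0702). A mean of at least 5 FPKM ended 5: interferon genes in shLuci+OGD vs shLuci (0.115) and shRac1+OGD vs shRac1 (0.133), contractile genes (0.135) and HIF targets (0.0821) in the latter, and NF-kB targets in the interaction (0.147). No filter ended 2: these HIF targets (0.0619) and interferon genes in shLuci+OGD vs shLuci (0.0524). Library weights ended the ribosomal list in shLuci vs BMSC (0.752) and trophic factors in shRac1+OGD vs shLuci+OGD (0.0529), which only the compared groups ended too (0.0912). The ribosomal list in shLuci vs BMSC reversed without BMSC replicate 2 (0.00497, upward), while its downward call ran from 1.7e-09 without BMSC replicate 1 to 0.00574 without shLuci replicate 2. The cause of the reversal was not tested.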

Other observations

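The authors' deposited lists can be set beside the calls made here, but both come from the same libraries. As the lists were also cut on fold and p-value, a shared direction was to be foreseen and is not separate evidence. For shLuci vs BMSC they hold 390 higher and 199 lower genes, and 99.5% of the tested ones in each direction were called in the same direction here, although only 118 and 57 of them have a q-value below 0.05 in the authors' own lists. The calls made here rest on the spread pooled over all groups, and a fit to these groups alone called 181 genes. For the hairpin contrast after OGD they hold 317 higher and 241 lower genes, of which 77.1% and 83.4% of those tested were called, and 263 and 195 have such a q-value. Of the 6 comparisons the authors made, 3 set a group against the libraries labelled shRac1. They include shLuci+OGD vs shRac1 and shRac1+OGD vs BMSC, but neither shLuci+OGD vs shLuci nor shRac1+OGD vs shRac1. Under the matching that left 38 interaction genes, the included pairs would be the OGD comparisons within each hairpin. A choice of comparisons is no measurement, so it does not decide whether the sample titles hold.

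Polr2l was listed at 0 in 4 libraries, replicate 1 of each infected group, and at 12.6 to 45.4 FPKM in the others, and Zswim8 at 0 in BMSC replicate 2 and at 11.2 to 15 FPKM elsewhere. In BMSC replicate 2 the 100 most abundant genes held 33.7% of the summed FPKM, against 26.5% to 28.6% in the other libraries. Its ribosomal protein genes had a median log2 deviation of 1.22 from the other BMSC libraries, its matrix genes one of -1.08 and its mitotic genes one of -0.45.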
